A study of Homo sapiens with 6 samples.

How the data were processed

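RNA-seq was run on total RNA of Y79 retinoblastoma cells in 6 libraries, 3 labelled shNC and 3 labelled shSUZ12. RNA was extracted with Trizol and libraries were made with an NEBNext Ultra kit, per the labels' protocols. The authors deposited 1 table of raw read counts per gene, with a gene symbol per line and a column per library. FastQC, STAR and HTSeq and the genome build hg38 are named in the submitters' processing notes. Versions, the gene annotation, the strand setting of the counting and any filter are not given in the sources used here. Columns were matched to samples by name. The values were whole numbers with a different total in each library, and the table had 0 lines that name no gene. Where counting takes no account of strand, reads of overlapping genes on opposite strands cannot be told apart. Counts of genes with near-identical copies, such as ribosomal protein genes with their pseudogenes, of overlapping mitochondrial genes, and of RPS10, which shares exons with a read-through gene, are uncertain because such reads can fit more than 1 gene.

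All 19932 symbols were found in GENCODE release 29 (hg38 coordinates), 19907 of them as protein-coding genes. That release gave gene identifiers, positions, the longest transcript per gene and its GC content. It may differ from the annotation used for counting.

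The counts were analysed as deposited in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups given (minimum count 10, minimum summed count 15), libraries were scaled by trimmed mean of M-values (TMM), and groups were compared by the robust quasi-likelihood test with no covariate. p-values were adjusted by the Benjamini-Hochberg method over all 12064 tested genes, with a threshold of 0.05. Normalised CPM are counts per library divided by the TMM-scaled library size and multiplied to the CPM scale. Normalization factors were 0.862 to 0.871 in shNC and 1.14 to 1.16 in shSUZ12. A set test, camera of limma 3.58.1 with a preset correlation of 0.01 between genes, was run on the 41 of 42 gene lists with at least 5 tested members, and adjusted over these. The lists held 1396 members taken from textbook knowledge, of which 1389 were in the table.

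The design, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. By that rule the text names SUZ12, then the 12 genes with the highest and the 12 with the lowest log2 change. These had to be called, reach a mean of 5 CPM in the higher group, show no overlap between the groups and carry an approved symbol. From each list up to 4 called members with the smallest p follow, up to 2 in each direction, with ACTB, GAPDH and TBP as controls. Genes outside this rule are said to be so where named, and 1 gene that the rule takes is not reported here. For a gene at 0 in all libraries of a group, no fitted fold is given, and bounds use a floor of 3 counts over the group, or 0.228 CPM in shNC and 0.0869 CPM in shSUZ12. If 35 shNC reads stand for 1 molecule, as in the molecule equivalents below, the shNC floor is 7.99 CPM.

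Alternatives were other scalings (RLE, upper quartile, library size alone), DESeq2 1.42.0, limma-voom, other filters, the 10 most abundant genes left out, the replicate number as a block, a test against a fold of 1.5, a threshold of 0.01, and each library left out in turn. For gene lists they were camera with an estimated correlation, fry, and the same changes of scale and samples. Alternatives added after seeing the data were the sum of the 3 shNC libraries as 1 library with shSUZ12 replicates 2 and 3 summed, genes read in all 6 libraries, smooth trends of each library on transcript length and GC content as offsets (for gene lists with the preset and with an estimated correlation), and molecule equivalents. For the last, summed shNC counts were divided by 35, the median summed count of the 369 genes read in shNC and at 0 in all shSUZ12 libraries.

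The tests were checked on simulated data for the comparison of shSUZ12 with shNC. Counts of 12064 genes were drawn from the observed means, dispersions and library sizes, with 100 genes changed 1.5-fold and 100 changed 2-fold. The edgeR test recovered 66% of the former and 83% of the latter, and 6.84% of its calls were false. In the same data camera called a simulated list of 40 shifted genes, and 0.5% of 200 random lists passed 0.05. The simulated libraries vary as replicates do and do not hold the closeness of the shNC libraries described with the data. Genes were drawn independently, so the check does not cover lists of correlated genes, such as the ribosomal list (estimated correlation 0.668).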

Results

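RNA of Y79, an established human retinoblastoma cell line, was sequenced in 2 groups of 3 libraries. One group carried the label shSUZ12, for a knockdown of SUZ12, and the other the label shNC, the comparison group. SUZ12 is a core subunit of Polycomb repressive complex 2 (PRC2), which methylates lysine 27 of histone H3 (H3K27). The comparison asks which transcripts differ in these cells when SUZ12 is knocked down. The deposited table held raw read counts of 19932 genes. The shNC libraries held 4784159, 5065073 and 5306605 counts, and the shSUZ12 libraries held 9257983, 10376415 and 10337529, so that depth and group went together. Nothing in the labels says that the 3 libraries of a group came from separate cultures, and p-values therefore measure only the spread between these libraries, which may be technical.

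The shNC libraries stood apart from the shSUZ12 libraries in how reads were spread over genes. Between 11113 and 11121 genes had reads in each shNC library, against 14170 to 14339 in each shSUZ12 library. Only 247 genes had 1 to 9 reads summed over the 3 shNC libraries, against 2086 genes over the 3 shSUZ12 libraries. A gene was mostly read in all 3 shNC libraries or in none, with 165 genes read in 1 or 2 of the 3, against 1697 genes in shSUZ12. In all, 1211 genes with a mean of 20 or more counts in shSUZ12 had 0 reads in every shNC library, and 91 genes showed the reverse. Counts of the 3 shNC libraries differed pairwise by little more than sampling noise, with a chi-square per degree of freedom of 1.36 to 1.44 over genes with 20 or more summed counts. Replicates 2 and 3 of shSUZ12 were as close, at 1.37, whereas replicate 1 differed from them at 8.61 and 9.02. No pair was free of a difference by the chi-square test, and each group was kept at 3 libraries.

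**Figure D1:**
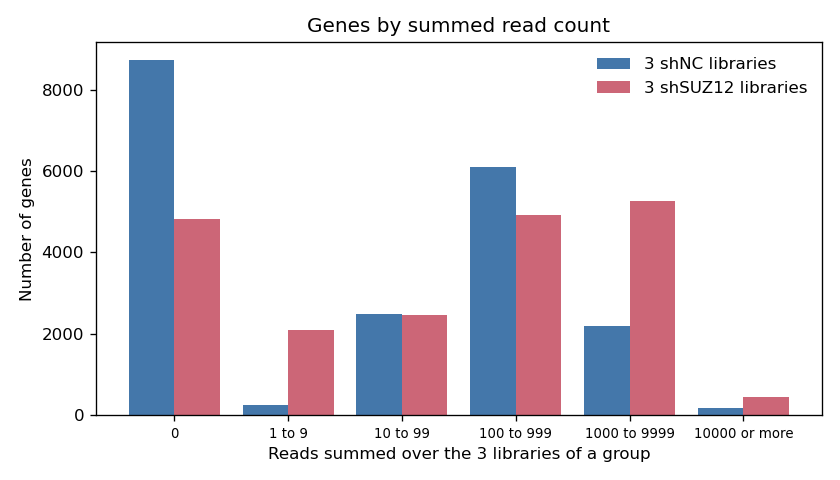
Number of genes (vertical axis) by the reads summed over the 3 libraries of a group (horizontal axis), for shNC (blue) and shSUZ12 (red). At 1 to 9 summed reads there were 247 genes in shNC and 2086 in shSUZ12, and at 0 reads 8731 and 4809.

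SUZ12 transcripts were lower in the shSUZ12 group, at 35.3 ± 3.62 CPM (normalised read counts; SD, n = 3) against 77.1 ± 1.48 (SD, n = 3) in shNC, a 2.18-fold difference. EED, which with SUZ12 forms the PRC2 core, was also lower, at 34.4 ± 2.26 against 61.5 ± 3.83 CPM (SD, n = 3). EZH2, the catalytic subunit of PRC2, was 3.42-fold higher in shSUZ12. The accessory subunit JARID2 was 3.78-fold higher. LCOR, which encodes a nuclear receptor corepressor and, as another isoform, an accessory protein of PRC2, was 3.79-fold higher as a gene, and gene-level counts do not separate these isoforms. Of 73 ribosomal protein genes 71 were lower and of 49 nuclear oxidative phosphorylation genes 45 were lower, whereas 25 of 32 sterol and fatty acid synthesis genes were higher.

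SUZ12 (ENSG00000178691.10; chromosome 17, 31937018 to 32001045 in hg38) had 325, 335 and 353 counts in the shNC libraries and 329, 451 and 446 in the deeper shSUZ12 libraries. Its log2 change was -1.12 (SE 0.0946, adjusted p = 1.57e-09, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), and all 3 shSUZ12 libraries lay below all 3 shNC libraries. Scaled by library size alone the log2 change was -0.71. A fall of this size was common, with 2854 of 12064 tested genes called lower at a log2 change below -1. In 87.5% of tested genes the 2 groups did not overlap, so these values do not single SUZ12 out. Reads shared with SUZ12 pseudogene copies could not be separated in gene-level counts.

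As 86.6% of all tested genes were called, a count of called members, here and below, does not by itself set a list apart. Of the 13 genes of the PRC2 list tested, LCOR among them, 8 were higher and 3 lower in shSUZ12, and 11 passed when adjusted over the list alone. With transcript length and GC content as offsets, a setting chosen after seeing the data, 6 were higher and 7 lower, and the median log2 change turned from 0.78 to -0.20. EZH2, named here after its value was seen, had a log2 change of 1.77 (SE 0.0861), JARID2 one of 1.92 (SE 0.0776) and EED one of -0.84 (SE 0.0958). With the shNC counts as molecule equivalents, where counting error is larger by construction, EED had a log2 change of -0.80 and was not called (adjusted p = 0.0783). The list as a whole did not pass the competitive set test (camera, adjusted p = 0.356). Among 21 subunit genes of Polycomb repressive complex 1, 15 were higher and 4 lower, 19 when adjusted over the list alone, with a camera adjusted p of 0.121. With length and GC offsets 12 were higher and 4 lower, and the median log2 change of that list went from 0.59 to 0.30. BCORL1 (log2 change 2.64) and PHC3 (1.96) were among the higher members and PCGF6 (-1.28) among the lower.

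**Figure D2:**
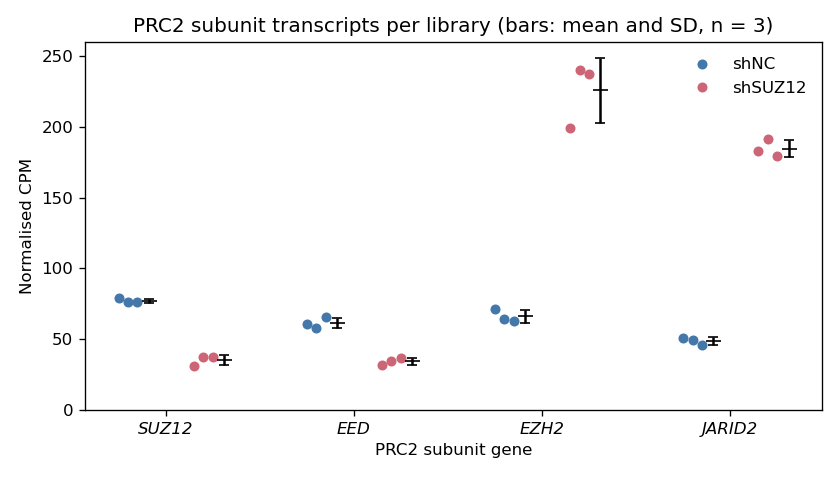
Normalised CPM (vertical axis) of 4 PRC2 subunit genes (horizontal axis) in each shNC (blue) and shSUZ12 (red) library, with the mean and SD of the 3 libraries in black. SUZ12 and EED lay lower in all 3 shSUZ12 libraries, and EZH2 and JARID2 lay higher in all 3.

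The list of H3K27 demethylases and trithorax-COMPASS subunits, chromatin regulators that act against Polycomb repression, had 18 members higher and 3 lower of 22 tested, 21 when adjusted over the list alone. The histone methyltransferase genes ASH1L and KMT2D rose from 8.12 ± 0.651 to 235 ± 18.5 CPM and from 20.2 ± 2.89 to 208 ± 4.16 CPM (SD, n = 3). DPY30 and ASH2L, shared subunits of the COMPASS complexes, fell, with log2 changes of -2.48 (SE 0.0973) and -1.11 (SE 0.099). Camera called the list higher (adjusted p = 0.0131), and the call was lost with an estimated correlation (adjusted p = 0.325 with an estimated correlation). The median transcript of this list was long, at 7672 bases, and with length and GC offsets the list was not called (adjusted p = 0.307), with 13 members higher and 6 lower.

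Known targets of Polycomb repression that were tested did not move one way. Of 124 developmental transcription factor genes 59 passed the expression filter, and of 39 HOX genes 11 did. The members left out by the filter were not tested, so the lists do not cover targets with few or no reads. Of 59 developmental transcription factor genes tested, 28 were higher and 24 lower, 52 when adjusted over the list alone (camera adjusted p = 0.736), and 14 members had 0 reads in all shNC libraries against 5 in all shSUZ12 libraries. The median log2 change of that list was 0.28, was 0.16 with molecule equivalents, and turned to -0.23 with length and GC offsets. LHX3 rose from 225 ± 8.63 to 465 ± 42.9 CPM, while EN2 fell from 26.6 ± 2.93 to 0.265 ± 0.159 CPM (SD, n = 3). Of 11 HOX genes tested, all passed when adjusted over the list alone, with 4 higher and 7 lower (camera adjusted p = 0.342). HOXC4 rose by a log2 change of 1.93 (SE 0.176), and HOXD13 (-4.67, SE 0.42) and HOXA10 (-3.54, SE 0.377) fell, and with molecule equivalents their log2 changes were -4.79 and -3.40 and not called (adjusted p = 0.0868 and 0.142). The shNC means of HOXC4, HOXD13 and HOXA10, at 5.83, 4.82 and 5.91 CPM, lay under 7.99 CPM, the shNC floor in molecules. The size of these 3 changes is therefore uncertain. The mean over HOX genes was -0.40 and the median -2.37, and the median was -2.48 with molecule equivalents. Of 16 genes tested near SUZ12 at 17q11.2, 8 were higher and 5 lower, 13 when adjusted over the list alone (camera adjusted p = 0.571). UTP6, adjacent to SUZ12, and COPRS, which lies beyond UTP6, fell by log2 changes of -1.14 and -1.87, and CDK5R1 rose by 3.68.

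Transcripts of the translation and respiration machinery were lower. Of 73 cytosolic ribosomal protein genes, 71 were lower and 1 higher, 72 when adjusted over the list alone. RPL10 fell from 9423 ± 31.3 to 2083 ± 33.1 CPM and RPL15 from 4467 ± 64.7 to 1016 ± 16.1 CPM (SD, n = 3). The higher member, RPS10, was listed at 0 in all shNC libraries, and was at least 22.3-fold higher against a floor of 3 reads. With 3 molecules of 35 reads each as the floor, chosen after seeing the data, the bound was 0.637-fold, which shows no rise. Of 49 nuclear genes of oxidative phosphorylation, 45 were lower, and 47 passed when adjusted over the list alone. NDUFA4 and COX6B1 fell 5.70-fold and 4.89-fold, and COX6B1 was not called with length and GC offsets (log2 change -0.09, adjusted p = 0.118). All 13 mitochondrially encoded genes were lower, also when adjusted over the list alone, with MT-ND2 at 207 ± 18.8 against 4202 ± 46.3 CPM and MT-CO3 at 343 ± 28.7 against 2884 ± 92.7 CPM (SD, n = 3). Camera called the 3 lists lower (adjusted p = 1.90e-22, 1.05e-13 and 2.84e-07), and all 3 calls were lost with an estimated correlation (adjusted p = 0.356, 0.356 and 0.18 with an estimated correlation). These transcripts are short. The longest annotated transcript per gene had a median of 1872 bases in the ribosomal list, 1587 in the nuclear list and 784 in the mitochondrial list. With length and GC offsets, 61 ribosomal protein genes were lower and 8 higher (median log2 change from -2.01 to -1.18), and 34 nuclear oxidative phosphorylation genes were lower and 10 higher (from -1.63 to -0.78). With the same offsets, 6 mitochondrially encoded genes were lower and 4 higher, their median log2 change was -0.49, and the list was no longer called (camera adjusted p = 0.564).

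MYC targets and ribosome biogenesis genes were lower as a list (camera adjusted p = 0.00462; adjusted p = 0.202 with an estimated correlation), with 28 members lower and 8 higher of 43, 36 when adjusted over the list alone. With length and GC offsets the list was not called (adjusted p = 0.104). LDHA and CCT3 fell 4.28-fold and 2.36-fold, and TFRC and CAD rose 2.64-fold and 2.26-fold. With length and GC offsets the rise of CAD was lost (log2 change -0.0096, adjusted p = 0.868). Mitosis and G2-M genes were also called lower (camera adjusted p = 0.0276; adjusted p = 0.356 with an estimated correlation), with 22 members lower and 13 higher of 45, 35 when adjusted over the list alone. Scaled by library size alone, 21 members were higher and 16 lower, the median log2 change turned from -0.22 to 0.19, and the call was lost (adjusted p = 0.145), as it was with length and GC offsets (0.447). CKS1B and CKS2, small partners of cyclin-dependent kinases, fell 4.12-fold and 2.96-fold, and TOP2A and CENPF rose 2.56-fold and 2.12-fold. With length and GC offsets CKS2 turned to a log2 change of 1.12 (adjusted p = 2.54e-14). Among 45 E2F target and DNA replication genes, 16 were higher and 20 lower, 36 when adjusted over the list alone (camera adjusted p = 0.373). Scaled by library size alone, 26 were higher and 14 lower, and the median log2 change turned from -0.15 to 0.26. CLSPN (log2 change 3.64) and POLE (1.89) rose, and TK1 (-2.35) and PCNA (-1.61) fell, with PCNA at -0.07 and not called with length and GC offsets (adjusted p = 0.310).

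Sterol and fatty acid synthesis genes were higher, with 25 members higher and 6 lower of 32, 31 when adjusted over the list alone (camera adjusted p = 0.000754; adjusted p = 0.202 with an estimated correlation). FASN, the fatty acid synthase gene, rose from 196 ± 8.25 to 1856 ± 97.2 CPM, and SQLE, which encodes squalene epoxidase, rose from 89.7 ± 0.809 to 540 ± 12.3 CPM (SD, n = 3). TM7SF2 and PMVK of the same pathway fell 5.30-fold and 5.28-fold. Heat shock genes were higher, with 11 members higher and 2 lower of 13, all of which passed when adjusted over the list alone (camera adjusted p = 0.0198; adjusted p = 0.325 with an estimated correlation). The chaperone genes HSP90AA1 and DNAJB1 rose 4.53-fold and 3.11-fold, and HSPE1 fell 1.37-fold. HSPE1 was not called when scaled by library size alone (log2 change -0.04) and turned to 1.52 with length and GC offsets (adjusted p = 1.87e-17). With these offsets camera, at its preset correlation, called both lists (adjusted p = 1.07e-05 for each; adjusted p = 0.550 and 0.551 with an estimated correlation), and with summed libraries the heat shock list was not called (adjusted p = 0.155).

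Wnt signalling and synapse and axon genes lay at the threshold of camera (adjusted p = 0.0496 for both; adjusted p = 0.356 and 0.461 with an estimated correlation). In the Wnt list 20 members were higher and 4 lower of 30, 24 when adjusted over the list alone, with 5 members at 0 in all shNC libraries. The coreceptor gene LRP5 rose 7.71-fold, and the receptor gene FZD8 fell by a log2 change of -1.18 (-1.24 and not called with molecule equivalents, adjusted p = 0.338). In the synapse and axon list 32 members were higher and 14 lower of 49, 46 when adjusted over the list alone, with 8 at 0 in all shNC libraries and 4 at 0 in all shSUZ12 libraries. SEMA6A rose 6.99-fold, and NRXN3 was listed at 0 in all shSUZ12 libraries. Neither list passed when scaled by library size alone (adjusted p = 0.0546 and 0.149) or with length and GC offsets (0.178 and 0.157). Among genes read in all 6 libraries the synapse and axon list passed (adjusted p = 0.00343) and the Wnt list did not (0.0856). With the replicate number as a block neither list passed (adjusted p = 0.0589 and 0.0854), nor did either pass without shSUZ12 replicate 1 (0.0800 and 0.0776), replicate 2 (0.0545 and 0.0705) or replicate 3 (0.0515 and 0.0546). The Wnt list was also lost without shNC replicate 1 (0.0545), the synapse and axon list without shNC replicate 2 (0.0524), and the mitosis list without shSUZ12 replicate 1 (0.0776).

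**Figure D3:**
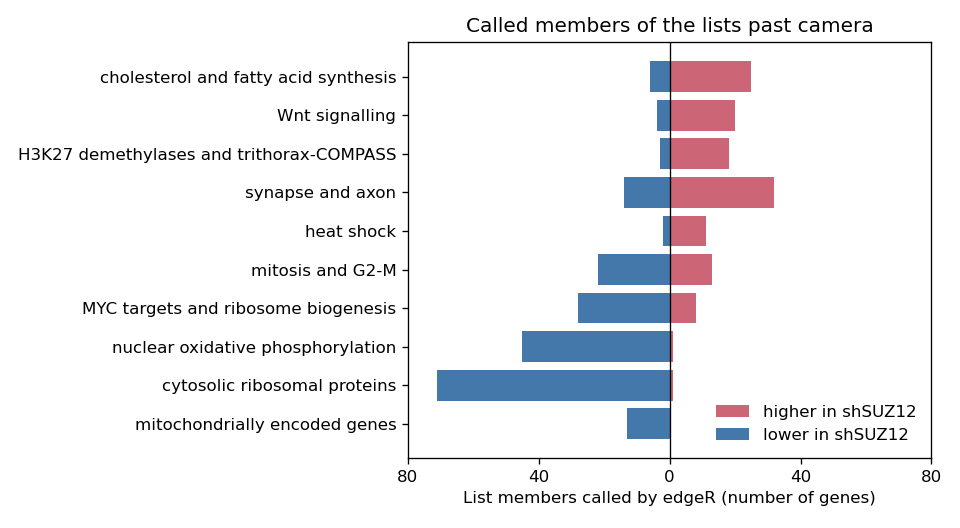
Number of list members called higher (red, right) or lower (blue, left) in shSUZ12 by edgeR, for the 10 gene lists past the threshold of camera at its preset correlation, none of which passed with an estimated correlation (smallest adjusted p = 0.18). The ribosomal protein list had 71 members lower and 1 higher, and the cholesterol and fatty acid list 25 higher and 6 lower.

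Retinal identity genes went both ways. Of 21 genes shared by rods and cones 13 were higher and 6 lower, of 13 rod genes 8 were higher and 3 lower, and of 16 cone genes 10 were higher and 4 lower (camera adjusted p = 0.373, 0.373 and 0.533; 19, 11 and 14 members passed when adjusted over the list alone). Of these members 6, 5 and 5 had 0 reads in all shNC libraries. Among genes read in all 6 libraries 6 shared genes were higher and 5 lower, 3 rod genes higher and 3 lower, and 5 cone genes higher and 4 lower, and the median log2 changes went from 0.87 to 0.04, from 2.44 to -0.08 and from 0.67 to 0.21. That filter takes out the members at 0 in all shNC libraries. The fall of these medians is therefore partly built in and does not test the change. RBP3, which encodes the retinoid-binding protein of the interphotoreceptor matrix, rose from 7.37 ± 0.293 to 107 ± 5.16 CPM, and the recoverin gene RCVRN rose from 125 ± 6.57 to 344 ± 13.4 CPM (SD, n = 3). RDH8 and the cone transducin gene GNB3 fell 5.44-fold and 2.56-fold. Of 19 retinal progenitor genes 9 were higher and 6 lower, 15 when adjusted over the list alone (camera adjusted p = 0.736), with SIX3 higher (log2 change 1.82) and ID1 lower (-2.55). Of 19 genes known as drivers of retinoblastoma 15 were higher and 2 lower, 17 when adjusted over the list alone (camera adjusted p = 0.0820). With length and GC offsets 12 were higher and 3 lower, and the median log2 change of the driver list went from 0.92 to 0.30. Without shSUZ12 replicate 1 that list was called higher (adjusted p = 0.0394), and over all 6 libraries it had an adjusted p = 0.356 with an estimated correlation. MDM4 rose 4.08-fold, ARID1A rose by a log2 change of 2.39, and SKP2 fell by a log2 change of -0.95.

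The genes with the largest fitted changes were listed at 0 in one group. The 12 at the upper end, PLXNA1, CEP290, ZXDC, CLSTN3, CNNM3, ADAM17, HDAC10, GRIP2, PLA2G6, P2RX2, ATP2B3 and MYO5A, had 0 reads in every shNC library and 50.6 to 85.6 mean CPM in shSUZ12. Against a floor of 3 counts over the group, PLXNA1 was at least 375-fold and MYO5A at least 222-fold higher. The 12 at the lower end, GATA3, SNTG1, NRXN3, FAM9B, C2orf91, NTNG1, SUSD4, PRAMEF17, HNF4A, KRT14, C12orf56 and KRT6A, had 0 reads in every shSUZ12 library and 10.5 to 24.8 mean CPM in shNC. GATA3 was at least 285-fold and KRT6A at least 121-fold lower. Such floors cover counting error of independent reads only. With 3 molecules of 35 reads each as the shNC floor, a setting chosen after seeing the data, PLXNA1 was at least 10.7-fold and MYO5A at least 6.33-fold higher. The bounds of the lower-end genes rest on shNC reads and were not recomputed for molecules, so they may be too large. Among genes read in all 6 libraries, a set taken after the values were seen, AEBP1 (66.7 ± 6.64 against 0.471 ± 0.432 CPM), HSPG2 (194 ± 3.40 against 2.10 ± 0.681) and NOTCH1 (236 ± 9.14 against 5.92 ± 1.79) rose (SD, n = 3). The shNC means of AEBP1, HSPG2 and NOTCH1 lay under 7.99 CPM, the shNC floor at 3 molecules of 35 reads each. The size of these rises is therefore uncertain, and the SD does not cover this. TCF23 and EN2 fell in that set, with TCF23 at 0.214 ± 0.225 against 36.0 ± 3.75 CPM (SD, n = 3).

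Common reference genes did not hold level. Of 15 tested, 10 were lower and 4 higher, 14 when adjusted over the list alone (camera adjusted p = 0.0955). Scaled by library size alone, 7 were lower and 6 higher. GAPDH fell from 18033 ± 217 to 3619 ± 173 CPM (SD, n = 3) and PPIA fell 3.33-fold. ACTB had a log2 change of -0.49 (SE 0.0529), which was -0.08 and not called when scaled by library size alone, and -0.10 and not called with length and GC offsets. TBP had a log2 change of -0.28 (SE 0.107, adjusted p = 0.0223), which turned to 0.13 when scaled by library size alone and to 0.64 with length and GC offsets, and was not called without shNC replicate 1 (adjusted p = 0.0933) or 2 (0.105).

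Over all genes, 5841 were higher and 4603 lower in shSUZ12 among 12064 tested (adjusted p under 0.05, edgeR quasi-likelihood test), which is 86.6% of the tested genes. In 87.5% of them the 2 groups did not overlap, where chance gives 10% for independent libraries, and 68.6% of genes did not overlap in simulated counts with no gene changed and the shNC libraries drawn from 1 pool of 433024 molecules. Of the calls, 55.9% were higher. Scaled by library size alone, 7035 genes were higher and 3541 lower, or 66.5% higher, and the median log2 change of all tested genes moved from 0.22 to 0.63. Of the higher genes 1261 had 0 reads in all shNC libraries, and of the lower genes 214 had 0 reads in all shSUZ12 libraries. The change rose with transcript length (Spearman's rho across genes 0.356, genes not being independent replicates). In the shortest 20% of genes the median was -1.09 with 68.1% of genes lower, and in the longest 20% it was 1.06 with 70.3% higher. With the shNC counts as molecule equivalents, chosen after seeing the data, 2768 genes were higher and 2075 lower.

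**Figure D4:**
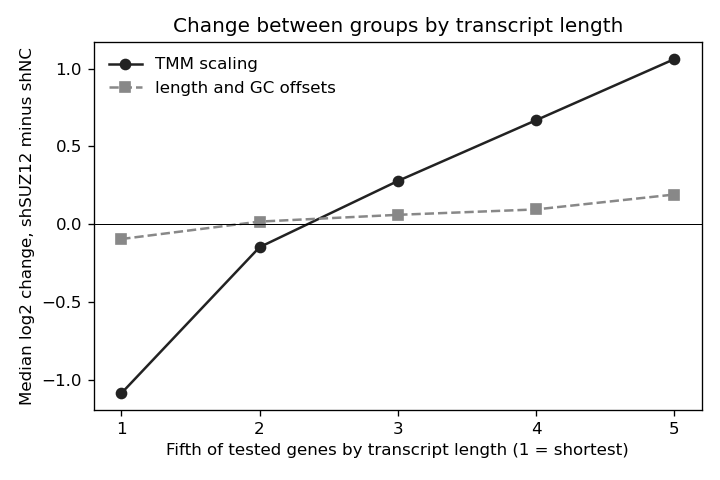
Median log2 change between shSUZ12 and shNC (vertical axis) in 5 equal groups of the tested genes by transcript length (horizontal axis, shortest first), with TMM scaling (circles) and with length and GC offsets (squares). With TMM scaling the median went from -1.09 in the shortest group to 1.06 in the longest, and with offsets from -0.10 to 0.19.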

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

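The settings with summed libraries, molecule equivalents, reads in all 6 libraries and length and GC offsets were chosen after seeing the data. SUZ12 stayed lower and called under every alternative run, with log2 changes from -1.42 (length and GC offsets) to -0.71 (library size alone), and -1.18 to -1.06 with 1 library left out. The counts of higher and lower genes stayed within 1.5 times of 5841 and 4603 under all alternatives but 1, with 5570 to 6155 higher and 4480 to 4770 lower when 1 library was left out. The exception was molecule equivalents, with 2768 higher and 2075 lower, where shNC counts are divided by 35 and 1 shNC library remains, so that counting error grows by construction. DESeq2 called 6357 higher and 4778 lower. With length and GC offsets 8546 of the 9184 genes called in both fits had the same direction.

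The 5 lists higher and 5 lower became 0 and 0 in camera with an estimated correlation, with length and GC offsets as well as without (without them, smallest adjusted p 0.18 and smallest unadjusted p 0.0044), and 24 and 13 in fry, which does not compare a list with other genes. The loss in camera does not by itself show correlated genes. Without offsets the estimate lay under the preset 0.01 for mitochondrial (0.004), MYC (-0.008), sterol (1.63e-05), heat shock (-0.023) and Wnt (0.003) genes. It lay above 0.01 for the other called lists, at 0.668 for ribosomal proteins. With independent simulated genes, the p of camera for the shifted list was 4.34e-65 at the preset and 6.5e-05 with an estimate. The number of higher lists was 3 with library size alone, 3 with a CPM of 1 in 3 libraries, 3 to 5 with 1 library left out (3 without shSUZ12 replicate 2 or 3), and 2 with length and GC offsets. The number of lower lists was 2 with length and GC offsets, where the ribosomal and nuclear oxidative phosphorylation lists stayed, 4 with library size alone, where the mitosis list was lost (adjusted p = 0.145), and 5 with any 1 library left out. Without shSUZ12 replicate 1 these 5 were not the same lists: mitosis was lost (0.0776) and glycolysis and hypoxia gained (0.0414), and among the higher lists the retinoblastoma drivers were gained (0.0394). Wnt and synapse lists, both at an adjusted p of 0.0496, account for each change from 5 to 3 higher lists. Beyond that the cause was not tested.

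The labels give no shared culture or batch, so the replicate numbers were not taken to pair the samples. Same-numbered shNC and shSUZ12 libraries did not deviate together (correlations -0.01, -0.02 and 0.02 across genes). The shNC libraries differed by little more than sampling noise, so these correlations could hardly show a pairing and do not exclude one. With the replicate block, 5827 genes were higher and 4587 lower, SUZ12 had a log2 change of -1.13, and 3 lists were higher and 5 lower.

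Of 88 other named genes checked, 76 kept direction and call under every alternative, and 85 under those planned. These 88 leave out some of the named genes at 0 in all libraries of a group. With length and GC offsets HSPE1 turned to 1.52, CKS2 to 1.12, CAD to -0.0096 and TBP to 0.64, and with library size alone TBP turned to 0.13; the cause was not tested. The depth of the shNC libraries, 4784159 to 5306605 counts, puts a gene at 0 there at up to 0.228 CPM if reads are independent and at up to 7.99 CPM if 35 reads stand for 1 molecule, and depth does not account for the 1211 genes at 0 with a mean of 20 or more counts in shSUZ12, where thinning to these totals would leave 2.68e-12 genes at 0.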

Other observations

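The tests of depth, shared molecules, a count filter and the length trend of oxidative phosphorylation genes were chosen after the result was seen, as were the settings with length and GC offsets, molecule equivalents, summed libraries and reads in all 6 libraries. Of 39 extracellular matrix and mesenchymal genes tested, 26 were higher and 11 lower in shSUZ12, 37 when adjusted over the list alone (camera adjusted p = 0.0955), and 11 members had 0 reads in all shNC libraries. Camera called that list higher with summed libraries (adjusted p = 0.0491) and among genes read in all 6 libraries (0.0151), at its preset correlation; over all tested genes the list had an adjusted p = 0.356 with an estimated correlation. The collagen genes COL6A2 and COL5A1 rose 23.8-fold and 7.75-fold, and the vimentin gene VIM fell by a log2 change of -0.92 (edgeR). Notch pathway genes were higher in 17 of 26 and lower in 8 (25 when adjusted over the list alone, camera adjusted p = 0.206). With length and GC offsets 13 were higher and 9 lower, and the median log2 change went from 0.88 to 0.20. The ligand gene JAG2 rose 6.06-fold and HES6 fell 2.01-fold. Hedgehog genes were higher in 6 of 11 and lower in 2 (8 over the list alone; 0.571), but with length and GC offsets 4 were higher and 5 lower. Of TGF-beta and BMP genes 18 of 29 were higher and 8 lower (26 over the list alone, camera adjusted p = 0.211). With those offsets 15 were higher and 9 lower, and the median log2 change went from 0.90 to 0.32. Immediate early genes were higher in 14 of 24 and lower in 7 (22 when adjusted over the list alone, camera adjusted p = 0.316). With length and GC offsets 12 of these genes were higher and 8 lower, and their median log2 change went from 0.52 to 0.24. Among them NPAS4 and NR4A1, both induced by neuronal activity, rose by log2 changes of 2.81 and 2.53, and ATF3 fell by a log2 change of -0.90.

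Markers of other retinal cells went both ways, with 9 higher and 8 lower of 18 inner retinal neuron genes, 5 and 4 of 10 Muller glia and astrocyte genes, and 4 and 3 of 7 retinal pigment epithelium genes (camera adjusted p = 1.00, 0.863 and 0.904; 17, 9 and 7 members passed when adjusted over the list alone). The median log2 change of inner retinal neuron genes was 0.07 and turned to -0.09 with upper-quartile scaling and to -0.22 with length and GC offsets. Of 17 neuronal markers of retinoblastoma subtype 2, 14 were higher and 3 lower, 17 over the list alone (0.121), with POU4F2 2.59-fold higher and UCHL1 3.11-fold lower. Fibroblast, blood and endothelial markers were higher in 6 of 9 and lower in 2 (8 over the list alone, camera adjusted p = 0.607). With length and GC offsets the subtype 2 list had 10 higher and 4 lower, and its median log2 change went from 1.247 to 0.718. The fibroblast, blood and endothelial list had 4 higher and 2 lower with these offsets, and its median went from 1.325 to 0.374. Stress and death lists were split, with 11 higher and 15 lower of 28 p53 targets, 11 and 18 of 32 apoptosis regulators, 3 and 4 of 10 CDK inhibitor and senescence genes, 12 and 14 of 30 unfolded protein and integrated stress response genes, and 11 and 18 of 36 glycolysis and hypoxia genes (camera adjusted p = 0.645, 0.182, 0.533, 0.560 and 0.121; 26, 29, 7, 26 and 29 over the list alone). Scaled by library size alone the balance of these lists turned, to 13 higher and 10 lower, 14 and 12, 6 and 4, 16 and 10, and 19 and 12 in the same order. The glycolysis and hypoxia list was called lower without shSUZ12 replicate 1 (camera adjusted p = 0.0414), and over all 6 libraries it had an adjusted p = 0.582 with an estimated correlation. Interferon-stimulated genes were higher in 10 of 19 and lower in 7 (17 over the list alone; 0.790), against 4 higher and 5 lower among those read in all 6 libraries. That filter takes out 5 members at 0 in all shNC libraries and 2 at 0 in all shSUZ12 libraries. Antigen presentation genes were higher in 4 of 5, B2M by 3.99-fold (4 over the list alone; 0.342). Of the 24 members only these 5 were tested, and 2 of them, HLA-B and NLRC5, had 0 reads in all shNC libraries. Against the floor in reads they were at least 13.5-fold and 10.1-fold higher. With the shNC floor in molecules, chosen after seeing the data, the bounds were 0.386-fold and 0.289-fold, which show no rise. Replication-dependent histone genes were lower in 12 of 20 and higher in 5 (17 over the list alone; 0.0955), but with length and GC offsets 11 were higher and 3 lower, and the median log2 change turned from -1.39 to 0.91. Imprinted genes were higher in 6 of 13 and lower in 6 (12 over the list alone; 0.737), with IGF2R 4.44-fold higher and NNAT 4.18-fold lower. Of 34 cancer-testis and germline genes 3 were tested, 1 higher and 2 lower, with no set test.

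Many genes were at 0 in all shNC libraries and read in shSUZ12. Lower depth is argued against, since thinning to the shNC totals would leave 2.68e-12 genes at 0 among those with a mean of 20 or more counts in shSUZ12, and 1211 were seen; so is a minimum-count filter on the shNC columns, since each held at least 557 genes with 1 to 9 reads. A candidate explanation is that the 3 shNC libraries were drawn from 1 pool of few captured and amplified molecules: only 2.21% of genes read in the summed shNC libraries had 1 to 9 reads, against 15.7% in shSUZ12 thinned to the same total. In a simulation of such a pool of 433024 molecules with no gene changed, edgeR called 63.6% of genes over the 6 libraries and 17 genes with molecule equivalents, but equal capture of all genes would leave 359 genes at 0, not 1211, so gene-specific loss or a real difference stays open. Release of Polycomb-repressed genes cannot be told apart from chance here, since 40% of 70 HOX and developmental factor genes with 10 or more summed shSUZ12 reads were at 0 in shNC, within the 28.6% to 48.6% of sets matched on level.

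Lower ribosomal protein and oxidative phosphorylation transcripts went with short transcripts. For the ribosomal list, a trend on the length and GC content of the longest annotated transcript is argued against as the whole cause. With offsets the list's median log2 change went from -2.01 to -1.18, with 61 members lower and 8 higher. The expressed transcript may be shorter than the longest annotated one, and the offsets then correct too little. Transcript length as the whole cause is therefore not excluded. With offsets camera at its preset correlation still called the list (adjusted p = 1.28e-10). The call rests on that preset, since with an estimated correlation it was lost both without offsets (adjusted p = 0.356) and with them (0.551). Scaling is argued against as well, since the median lay between -2.17 and -1.60 under TMM, RLE, upper-quartile and library-size scaling. For nuclear oxidative phosphorylation genes the median fell in size from -1.63 to -0.78 with offsets while the list stayed called at the preset correlation (adjusted p = 0.000506; 34 members lower and 10 higher) and not with an estimated correlation (adjusted p = 0.356 without offsets and 0.551 with them), so a length trend and a change of these genes cannot be told apart, and the mitochondrially encoded list was no longer called (adjusted p = 0.564; median -0.49, 6 members lower and 4 higher). A response of growth or metabolism to the knockdown may contribute and was not tested.

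SUZ12 itself may be less certain than its adjusted p suggests, given the shNC libraries. Counting error of few molecules as the cause is argued against, though narrowly at the upper quartile: with 29 molecule equivalents in shNC the adjusted p was 0.00634 (log2 change -1.11, SE 0.352), and with divisors at the lower and upper quartile it was 0.000165 and 0.0486. That fit holds 1 shNC library, so its spread between libraries comes from shSUZ12 alone and the lone shNC library is assumed to vary like those. A length trend is argued against, since with length and GC offsets the log2 change was -1.42 (SE 0.0791). The molecule equivalents assume equal capture of all genes. Among genes with a mean of 20 or more counts in shSUZ12, equal capture would leave 359 at 0 in shNC, and 1211 were seen. Counting error may therefore be larger than that fit allows, and the fit cannot decide the question. The 16 genes tested near SUZ12 went both ways, with 8 higher and 5 lower, and a cause other than the hairpin was not excluded.

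The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split, 1 of the 10, gave 10444 called genes and the highest of the others 0 in edgeR (3 genes at an unadjusted p under 0.05). Every other split mixes the groups, so a difference between them from any cause widens the spread within each side. The contrast in called genes therefore does not separate the knockdown from a difference in how the libraries were made. For gene lists, the real split, 1 of the 10, gave 10 called lists and the highest of the others 8.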
